A study of Homo sapiens with 12 samples.

How the data were processed

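AQ-seq small RNA libraries, made per the labels from 100 µg of total RNA extracted with TRIzol and sequenced on a NovaSeq 6000, were available for 12 samples of HCT116 and HEK293T cells rescued with DICER WT, dsRBD deletion or AA. The deposited values are raw counts, one table of counts per library, with a read count for each miRNA name and for each of 30 spike-in RNAs. The authors' processing notes name cutadapt, BWA and bedtools, with versions and order not given in the sources used here, and the builds hg38 and mm10, whose roles are not given. Which miRNA annotation was used and how reads that match several names were counted are also not given. Counts of near-identical names may therefore share reads, such as miR-1268a and miR-1268b, miR-151a-5p and miR-151b, miR-320a and miR-320b, let-7 members, and names made from several loci. The tables list 1854 miRNA names for HCT116 and 1611 for HEK293T, 1494 of them in both. The raw reads were not used here.

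The labels number the libraries of a group 1 and 2 without saying whether they come from separate cultures, so p-values measure the spread between these libraries only. Differences of 2 replicates of a group were compared across miRNAs between forms to see whether equal numbers belong together. The correlations in HCT116 were 0.147 (WT and deletion), −0.104 (WT and AA) and −0.0487 (deletion and AA), and in HEK293T −0.0258, −0.0675 and 0.0930, so the numbers were not used as pairs. Spike-in profiles, relative to the line's mean, correlated at 0.694 between replicates 1 of WT and deletion in HCT116 and at 0.0330 between replicates 2. Within groups they correlated at −0.388 (WT), −0.451 (deletion) and 0.208 (AA) in HCT116, and 0.356, 0.599 and 0.690 in HEK293T. Between groups in HEK293T, the deletion libraries correlated at −0.780 and −0.723 with WT replicate 2. With WT replicate 1 they correlated at 0.0315 and −0.470, and with the AA libraries at −0.818 to −0.602. Shared preparation of some libraries is thus not excluded. In HEK293T, a preparation difference of the size seen in the spike-ins cannot be told apart from an effect of the deletion.

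Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with ViennaRNA 2.7.2 and matplotlib 3.10.9. Spike-in reads, 0.272% to 1.55% of a library in HCT116 and 1.20% to 3.54% in HEK293T, were left out of library sizes and tests. For each line, names passing filterByExpr by group (minimum count 10) were scaled by TMM and tested with edgeR's quasi-likelihood F test on group means over all 6 libraries, which share the estimate of spread and leave 3 residual degrees of freedom. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Differences between the lines were tested as contrasts over all 12 libraries and the names listed for both lines. There were 9 comparisons of miRNA levels and 4 of arm use, each adjusted on its own. The spike-ins were also scaled by DESeq2 size factors and tested among themselves, with changes centred on the median spike-in. Adjusted p values in the text come from these edgeR tests unless another method is named, the SE of a log2 fold change is its size divided by the square root of F, and CPM are TMM-scaled.

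Arm use was tested per hairpin as the edgeR interaction of arm and group with library as a block, for hairpins with at least 10 reads per arm in at least 2 libraries. Lists of miRNAs were tested for the 4 comparisons with WT by camera with a preset correlation of 0.01, on lists with at least 5 tested names, with camera on an estimated correlation and fry beside it. Camera tests a list against the other miRNAs, and fry tests it against no change. The lists were the let-7, miR-10/99/125, miR-15/16, miR-23/27/24, miR-26, miR-29, miR-30, miR-148/152, miR-181, miR-200 and miR-221/222 families, the miR-17-92 cluster and paralogs, the miR-183, chromosome 14q32 and C19MC clusters, mirtrons, DROSHA-independent, DICER-independent (miR-451a), p53-responsive and alternative DICER cut (miR-324) miRNAs, markers of other tissues, and all 5p and all 3p names. Correlations of effects across miRNAs used a prior count of 2, with 1000 bootstrap draws and 100 simulated data sets in which only the shared WT libraries link the effects.

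The named-miRNA rule for the comparisons with WT took, among called names whose 2 groups did not overlap and whose mean over the line was at least 100 CPM, the 7 largest rises and 7 largest falls. It added the 6 most abundant names of the line, the most abundant members of each list discussed, miR-324-5p, miR-324-3p and miR-451a. For the other comparisons it took the 4 largest rises and falls, and for arms up to 5 hairpins in each direction with at least 100 CPM and miR-324. Samples, tests, lists, named-miRNA rule and most alternatives were fixed before the data were examined.

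Fixed in advance as alternatives were DESeq2 size factors in edgeR, library totals only, upper-quartile factors, no filter on low counts, a mean of at least 100 CPM, the DESeq2 Wald test, a replicate block, leaving out each library, the spread shared by all 12 libraries, and only the 4 libraries compared. For arms they were at least 50 reads per arm in every library and limma on log2 ratios with a pseudocount of 1, and for correlations a prior count of 10. Scaling to the spike-ins (the median of ratios over 30, or their total), edgeR's glmTreat against the largest spike-in change, and a replicate block with the numbers of the AA libraries crossed were chosen after seeing the data. The spike-in amount is not given, so spike-in scaling is an alternative and TMM the default.

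Hairpin positions and host genes are from GENCODE release 29 on GRCh38, the assembly that hg38 names, in which 1969 of the 1971 distinct miRNA names (99.9%) were matched. Mature arm coordinates were not used here. The 3 reads that a count of 0 allows are taken per library, and intervals and floors cover counting error only. Counts of the 2 libraries of each group differed by far more than counting error (chi-square per degree of freedom 12.6 to 98.9), so none is a copy of another. The tests were also run on simulated counts with known changes: with dsRBD deletion in HCT116 the edgeR test recovered 76.3% of 2-fold and 96.8% of 4-fold changes with 6.21% of calls false, with AA in HCT116 72.0% and 94.7% with 3.57%, with dsRBD deletion in HEK293T 67.7% and 96.8% with 4.35%, and with AA in HEK293T 67.7% and 97.9% with 3.05%. The test of deletion effects between lines recovered 33.7% and 67.0%, with 5.10% false. The arm interaction recovered 48.0% of 2-fold and 81.8% of 4-fold changes with 9.09% of calls false for dsRBD deletion in HCT116, 75.0% and 80.0% with 2.56% for AA in HCT116, 20.8% and 95.8% with 6.67% for dsRBD deletion in HEK293T, and 30.4% and 96.0% with 6.06% for AA in HEK293T. The simulated rises and falls were about equal in number and size, with no change shared by all miRNAs. These shares therefore do not cover errors that come from the choice of scaling.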

Results

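Small RNA was profiled by AQ-seq, a library protocol designed to reduce ligation bias, in HCT116, a human colorectal carcinoma line, and HEK293T, a human embryonic kidney line. DICER is the nuclease that cuts hairpin precursors into miRNA duplexes, and each line was rescued with 1 of 3 DICER forms. The forms were WT, a form with its double-stranded RNA-binding domain deleted (dsRBD deletion), and a form that the labels call AA without saying what was changed. Each of the 6 groups held 2 libraries, 12 in all. In HCT116 the miRNA reads per library were 4498886 and 4056722 with WT, 824987 and 1353117 with dsRBD deletion, and 3157018 and 3551705 with AA. In HEK293T they were 2791656 and 3552613 with WT, 1059778 and 1226813 with dsRBD deletion, and 2897843 and 1440770 with AA. At these depths 3 reads, the limit that a count of 0 allows, were 0.755 CPM in the deepest library and 3.10 CPM in the shallowest. CPM are reads scaled by library size times the TMM factor. Hairpin positions below are 1-based on GRCh38.

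With dsRBD deletion, HCT116 yielded 64.2 ± 0.736 miRNA reads per spike-in read (mean ± SD, n = 2), against 320 ± 65.9 with WT, 4.99-fold less. In HEK293T the deletion gave 28.2 ± 1.33 against 81.8 ± 1.21 with WT (n = 2 each), 34.5% of WT. AA lay between the other forms in both lines, at 208 ± 2.93 in HCT116 (64.8% of WT) and 51.6 ± 10.3 in HEK293T (63.1% of WT). In each of the 4 comparisons with WT the libraries of the 2 groups did not overlap, and the two-sided exact permutation p was 0.333, the smallest that 2 against 2 libraries allow. Taken alone, the 30 spike-ins gave shifts of the miRNAs by dsRBD deletion of −2.27 to −0.78 on the log2 scale in HCT116 and −3.06 to −0.25 in HEK293T, all below 0. For AA they gave −2.47 to 0.22 in HCT116, with 28 of 30 below 0, and −1.93 to 0.18 in HEK293T, with 26 of 30 below 0. The amount of spike-in RNA and the step at which it was added are not given in the sources used here, so these ratios are miRNA content per unit of RNA only if every library received the same amount.

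**Figure D1:**
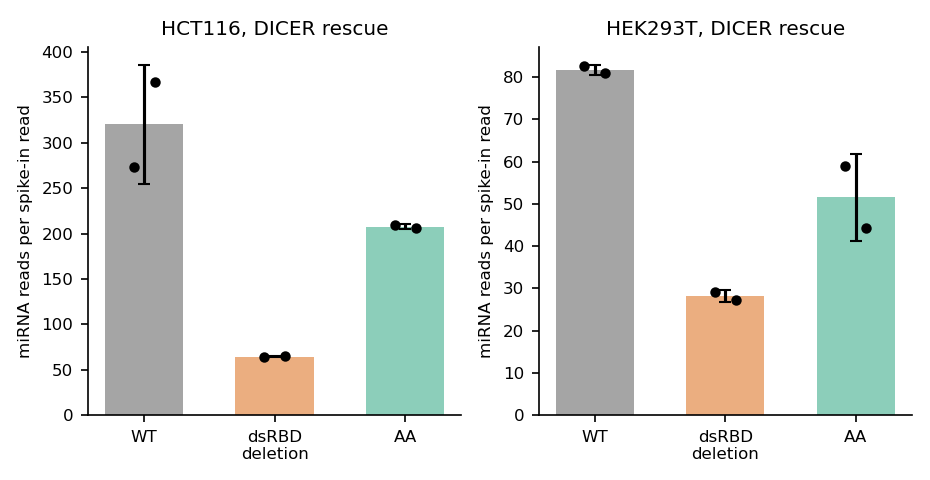
MiRNA reads per spike-in read (y axis) with each DICER form, as the mean and SD of 2 libraries (dots), in HCT116 and HEK293T. Bars are means; with dsRBD deletion they were 4.99-fold below WT in HCT116 and 2.90-fold in HEK293T, and with AA 1.54-fold and 1.59-fold.

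With the dsRBD deletion in place of WT, some miRNAs were almost emptied in HCT116 and others stayed at a similar level relative to the typical miRNA. The amount of each DICER form in the cells is not given in the sources used here. For both altered forms, an effect of the change itself therefore cannot be told apart from one of a different amount of DICER. MiR-331-3p (MIR331, chromosome 12, 95308420 to 95308513, intergenic on its strand) fell from 1582 ± 423 to 10.4 ± 1.63 CPM (mean ± SD, n = 2 each), a log2 fold change of −7.20 ± 0.28 (SE), while miR-27b-3p (MIR27B, chromosome 9, 95085445 to 95085541, intron of C9orf3) fell from 7526 ± 394 to 165 ± 3.87 CPM (−5.51 ± 0.14). MiR-484 (MIR484, chromosome 16, 15643294 to 15643372, exon of NDE1) fell from 1218 ± 188 to 30.1 ± 4.09 CPM (−5.36 ± 0.20). Of the most abundant miRNAs, miR-222-3p fell 18.8-fold, from 92260 ± 4227 to 4897 ± 831 CPM, whereas miR-21-5p was at 365086 ± 31263 TMM-scaled CPM with WT and 353905 ± 40720 with the deletion. As a share of all miRNA reads miR-21-5p rose, from 30.3% and 31.7% in the WT libraries to 44.9% and 41.4% in the deletion libraries. MiR-25-5p (MIR25, chromosome 7, 100093560 to 100093643, intron of MCM7) rose 9.78-fold, from 79.5 ± 6.82 to 780 ± 117 CPM. The edgeR adjusted p values were 6.4e-09 for miR-331-3p, 1.0e-09 for miR-27b-3p, 4.6e-09 for miR-484, 3.4e-09 for miR-222-3p, 3.9e-08 for miR-25-5p and 0.729 for miR-21-5p. For the first 5 the groups did not overlap, which the naming rule required of all but miR-222-3p. Of all tested names 82.5% had no overlap, against 33.3% by chance. Without deletion replicate 1 miR-21-5p was called lower (−0.31).

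Among called miRNAs of at least 100 CPM, the other largest falls in HCT116 were miR-615-3p (log2 fold change −7.69 ± 0.39), miR-3200-3p (−7.36 ± 0.38), miR-1180-3p (−5.55 ± 0.30) and miR-301a-3p (−5.50 ± 0.20). With the same limit the other largest rises were miR-1275 (1.88 ± 0.21), miR-6724-5p (1.79 ± 0.15), miR-30d-3p (1.79 ± 0.14), miR-7974 (1.77 ± 0.17), miR-1268a (1.70 ± 0.21) and miR-1268b (1.70 ± 0.20), of which the last pair have near-identical sequences and could share reads. Among abundant miRNAs, miR-29a-3p fell by 2.49 on the log2 scale, miR-221-3p by 1.64, miR-24-3p by 1.58 and miR-31-5p by 0.94. In all, 223 of 795 tested miRNAs were higher and 271 lower by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. These changes are relative to the typical miRNA. Scaled to library totals the split was 317 higher and 198 lower, and the median of all 795 moved from −0.01 to 0.52. Scaled to the spike-ins it was 7 higher and 598 lower, and the median was −1.78. Going from TMM to spike-in scaling lowered the typical name 3.39-fold. That is an offset between the 2 scalings and not a measured change of every miRNA. On the spike-in scale miR-25-5p was still called higher and miR-21-5p fell by 1.86, while miR-1275 (0.11), miR-6724-5p (0.00) and miR-30d-3p (0.01) did not differ and miR-7974, miR-1268a and miR-1268b stood at −0.06 to −0.07.

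With dsRBD deletion in HCT116 more 3p names were lower than higher, and more 5p names were higher than lower. The 311 tested 3p names had a median log2 fold change of −0.91, with 58 higher and 150 lower (59 and 150 adjusted over the list alone), and the 339 tested 5p names had 0.30, with 109 higher and 86 lower (109 and 85 adjusted over the list alone). On the spike-in scale both medians were below 0, at −2.65 and −1.44, and with library totals they were −0.38 and 0.84. Counted on the spike-in scale, 1 of the 3p names was higher and 273 lower, and 4 of the 5p names were higher and 247 lower. All 5 tested members of the DROSHA-independent list fell, among them miR-320a (−1.13 ± 0.13) and miR-320b (−1.29 ± 0.20), under each of the 6 scalings. The camera test with its preset correlation had adjusted p values of 3.8e-05 for the 3p arms (lower), 0.032 for the 5p arms (higher) and 0.043 for the DROSHA-independent list (lower), which was 0.112 with library totals. With the correlation estimated from the data these became 0.419, 0.416 and 0.971, and by fry they were 0.0025, 0.199 and 0.0093. Fry here tests for a shift of the list in 1 direction against no change, whereas camera tests it against the other miRNAs. Fry's mixed test, which counts changes in either direction, had adjusted p values of 4.9e-05, 6.1e-06 and 8.1e-04.

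Families split internally in HCT116. In the miR-23, miR-27 and miR-24 family miR-27a-3p fell by 3.38 on the log2 scale and miR-24-3p by 1.58, but miR-23a-3p by 0.54, and 4 of 11 members were higher and 5 lower. The miR-17-92 cluster and its paralogs had 6 of 21 higher and 10 lower, with miR-17-5p at −0.94 ± 0.11, miR-92a-3p at −0.51 ± 0.16 and miR-19b-3p at 0.46 ± 0.12. Of the let-7 family 7 of 19 were higher and 7 lower, with let-7i-5p at −0.76 ± 0.12, let-7a-5p at −0.10 ± 0.13 and let-7g-5p at 0.49 ± 0.12. On the spike-in scale these lists had 0, 2 and 0 members higher. The list medians turned with the scaling, from −0.26 to 0.27 (library totals) and 0.02 (upper quartile) for the miR-23, miR-27 and miR-24 family, from −0.08 to 0.47 and 0.21 for the miR-17-92 list, and from −0.10 to 0.42 and 0.21 for let-7. The calls of let-7g-5p and miR-19b-3p were lost without WT replicate 1 (0.26 and 0.22), that of let-7g-5p also without deletion replicate 1 (0.30), that of miR-19b-3p without deletion replicate 2 (0.28) and that of miR-92a-3p without deletion replicate 2 (−0.45). Without deletion replicate 1 let-7a-5p became called (−0.43). Adjusted over the list alone, these 3 lists had the same counts.

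MiR-324-5p and miR-324-3p, whose hairpin (MIR324, chromosome 17, 7223297 to 7223379, intergenic on its strand) is known for alternative DICER cutting, fell by 0.58 and 1.86 on the log2 scale in HCT116. MiR-451a, which is made without DICER (MIR451A, chromosome 17, 28861369 to 28861440), rose from 82.3 ± 3.95 to 186 ± 43.8 CPM, a log2 fold change of 1.19 ± 0.19 that became −0.59 on the spike-in scale. The edgeR adjusted p values were 0.0015 for miR-324-5p, 3.0e-06 for miR-324-3p and 3.0e-04 for miR-451a (n = 2 per group).

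In HEK293T, dsRBD deletion removed most of miR-93-5p and raised miR-193a-3p more than any other miRNA named by the rule. MiR-93-5p (MIR93, chromosome 7, 100093768 to 100093847, intron of MCM7) fell 85.5-fold, from 19920 ± 2681 to 233 ± 18.8 CPM (n = 2 each), and miR-1180-3p (MIR1180, chromosome 17, 19344506 to 19344574, intron of B9D1) fell 206-fold, from 434 ± 65.2 to 2.03 ± 0.375 CPM. MiR-331-3p fell 95.2-fold, from 394 ± 82.4 to 3.89 ± 4.25 CPM. The deletion libraries held 2 and 3 reads of miR-1180-3p and 1 and 9 of miR-331-3p, where 3 reads were 2.65 and 2.30 CPM. The folds of miR-1180-3p and miR-331-3p are therefore rough. MiR-193a-3p (MIR193A, chromosome 17, 31559996 to 31560083) rose 12.4-fold, from 1617 ± 405 to 20081 ± 696 CPM, and miR-19b-3p rose from 52938 ± 3774 to 247604 ± 949 CPM, so that it took 26.4% of all miRNA reads. The edgeR adjusted p values were 8.1e-09 for miR-93-5p, 1.6e-08 for miR-1180-3p, 2.0e-07 for miR-331-3p, 9.9e-08 for miR-193a-3p and 5.8e-07 for miR-19b-3p. Their groups did not overlap, which the naming rule required of all but miR-19b-3p. Of all tested names 89.0% had no overlap, against 33.3% by chance.

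The other largest falls in HEK293T among called miRNAs of at least 100 CPM were miR-615-3p (−7.58 ± 0.37), miR-375 (−6.68 ± 0.31), miR-1269b (−6.13 ± 0.36) and miR-345-5p (−6.12 ± 0.33), and the other largest rises miR-33b-5p (3.46 ± 0.26), miR-4286 (3.27 ± 0.20), miR-19a-5p (3.26 ± 0.20), miR-548a-3p (3.21 ± 0.21), miR-362-5p (3.13 ± 0.23) and miR-1271-5p (3.08 ± 0.27). These 6 rises and that of miR-193a-3p held on the spike-in scale, at 1.62 to 2.18. MiR-19b-3p (0.77) and miR-451a (2.22 ± 0.23 by TMM, 0.77 by spike-ins) also stayed higher, whereas miR-4521 went from 1.30 to −0.16. Of the remaining abundant miRNAs miR-16-5p fell by 1.19 and miR-92a-3p by 0.72, and miR-10a-5p (−0.03 ± 0.16) and miR-20a-5p (−0.33 ± 0.17) did not pass. MiR-324-3p fell by 1.34, while miR-324-5p rose by 0.63 ± 0.19, became −0.82 by spike-ins and was not called without WT replicate 2 (0.30) or without deletion replicate 1 (0.56) or 2 (0.59). By edgeR with Benjamini-Hochberg adjustment 225 of 626 miRNAs were higher and 248 lower. Scaled to the spike-ins 60 were higher and 386 lower. The median offset of names from TMM to spike-in scaling was −1.45. The spike-ins also moved against each other in this comparison. Scaled and tested among themselves, 17 of the 30 were called, with changes of up to 1.63 in size, against 0 of 30 by edgeR in the same comparison in HCT116, where 0 had an unadjusted p under 0.05. Tested by glmTreat against that largest spike-in change, an alternative chosen after the data were seen, 73 miRNAs were higher and 139 lower, among them the 7 rises named here, miR-19b-3p and miR-451a.

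**Figure D2:**
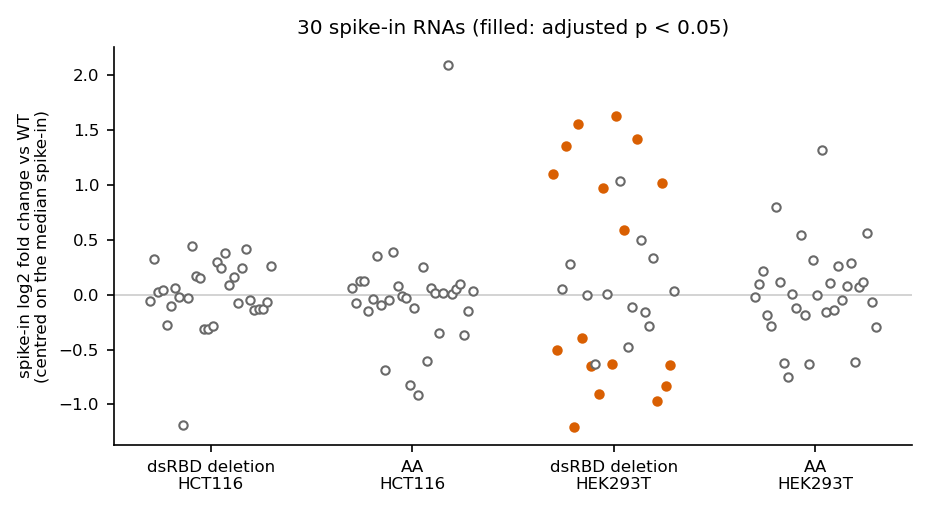
Log2 fold change against WT of each of the 30 spike-ins (dots, y axis), centred on the median spike-in, for both altered forms in both lines, with filled dots for adjusted p under 0.05. Changes reached 1.63 in size with dsRBD deletion in HEK293T, where 17 are filled, and 1.19 with dsRBD deletion in HCT116.

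With dsRBD deletion in HEK293T some families had mostly lower members, while others went both ways, such as the miR-17-92 list with 9 of 21 higher and 9 lower. Of the miR-181 family 8 of 9 were lower (9 adjusted over the list alone), with miR-181a-5p at −1.78 ± 0.17 and miR-181b-5p at −1.98 ± 0.19, and 5 of 6 members of the miR-148 and miR-152 list were lower. The DROSHA-independent list had all 5 lower, with miR-484 at −4.48 ± 0.24, miR-320a at −1.04 ± 0.21 and miR-320b at −1.21 ± 0.20. In the miR-23, miR-27 and miR-24 family miR-27b-3p fell by 3.10, miR-23b-3p by 2.37 and miR-24-3p by 0.72; in the miR-30 family miR-30a-5p fell by 3.60 and miR-30e-5p was not called (−0.24 ± 0.16). Let-7a-5p fell by 1.20 and let-7f-5p by 1.53, and let-7c-5p (0.56 ± 0.24) did not pass. The medians of the miR-181, miR-148 and miR-152, miR-30 and DROSHA-independent lists were below 0 under each of the 6 scalings. The camera test with its preset correlation called no list in this comparison, with smallest adjusted p values of 0.057 for the miR-181 family and 0.070 for the miR-148 and miR-152 list.

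**Figure D3:**
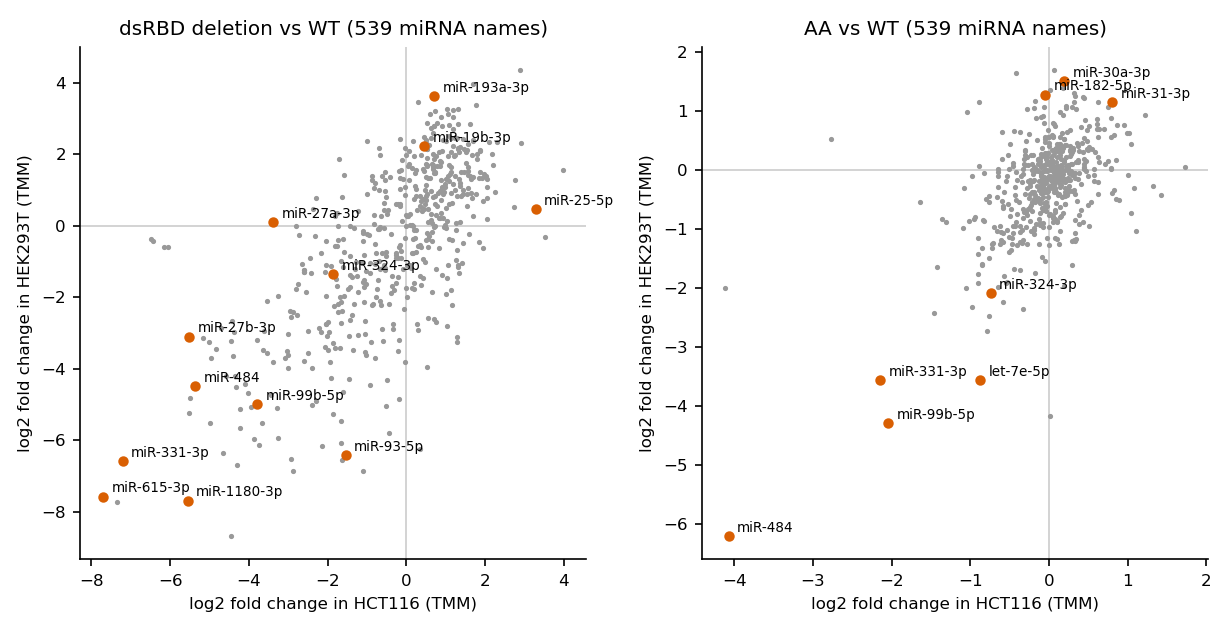
Log2 fold change against WT in HCT116 (x axis) and HEK293T (y axis) for dsRBD deletion and AA, 1 point per miRNA tested in both lines (539), with some named miRNAs labelled. Across miRNAs the effects correlated with r = 0.719 for dsRBD deletion and r = 0.552 for AA, and miR-331-3p was low on both axes in both plots.

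AA lowered a few miRNAs of HCT116 strongly, and most of the others were not called. MiR-484 fell 16.8-fold, from 1218 ± 188 to 72.6 ± 1.05 CPM (n = 2 each), miR-331-3p fell 4.43-fold, from 1582 ± 423 to 357 ± 37.9 CPM, and miR-99b-5p (MIR99B, chromosome 19, 51692612 to 51692681, intron of SPACA6) fell 4.12-fold, from 2476 ± 216 to 601 ± 7.38 CPM. Among called miRNAs of at least 100 CPM the next largest falls were miR-3200-3p (−1.46 ± 0.19), miR-361-3p (−1.09 ± 0.13), miR-3615 (−1.05 ± 0.14) and miR-125b-5p (−0.98 ± 0.16), and the rises with that limit were miR-196b-3p (1.04 ± 0.16), miR-7-1-3p (0.85 ± 0.13), miR-4521 (0.85 ± 0.20) and miR-31-3p (0.80 ± 0.12). Of the abundant miRNAs only miR-222-3p changed (−0.72 ± 0.13); miR-21-5p (−0.22 ± 0.11), miR-31-5p (−0.13 ± 0.10), miR-221-3p (−0.21 ± 0.11), miR-29a-3p (0.09 ± 0.16) and miR-24-3p (0.07 ± 0.10) did not pass. MiR-324-3p fell by 0.74, and miR-324-5p (0.12 ± 0.12) and miR-451a (0.11 ± 0.19) did not pass. The edgeR adjusted p values were 1.6e-07 for miR-484, 8.7e-05 for miR-331-3p, 1.7e-05 for miR-99b-5p, 0.0058 for miR-222-3p and 0.014 for miR-324-3p.

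By edgeR with Benjamini-Hochberg adjustment 10 of 795 miRNAs were higher and 49 lower with AA in HCT116. Leaving out an AA library leaves 1 in that group and less power. Calls lost in this way need not mean that the effect itself moved, so the log2 fold changes are given in brackets. Without AA replicate 1 the calls of miR-196b-3p (0.93), miR-7-1-3p (0.82), miR-4521 (1.07), miR-31-3p (0.74), miR-3615 (−1.07), miR-125b-5p (−0.98), miR-222-3p (−0.72) and miR-324-3p (−0.79) were lost, and without AA replicate 2 those of miR-4521 (0.58), miR-222-3p (−0.73) and miR-324-3p (−0.69). The split was 22 higher and 23 lower with library totals (median 0.15), 11 and 23 with upper-quartile factors (median 0.11), 2 and 270 with the spike-ins (median −0.63) and 5 and 181 with the spike-in total (median −0.46). On the spike-in scale the 4 named rises were 0.20 to 0.45 and none was called. Tested by glmTreat against the largest spike-in change (2.09), 1 miRNA was called, miR-484. By edgeR 0 of the 30 spike-ins were called in this comparison, and 0 had an unadjusted p under 0.05.

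Of the lists, the mirtrons, which are spliced rather than cut by DROSHA, had 5 of 15 lower with AA in HCT116, or 2 higher and 8 lower adjusted over the list alone. Their median was −0.86, and it was below 0 under each of the 6 scalings. The most abundant members, miR-877-5p (−0.66 ± 0.24) and miR-877-3p (−0.26 ± 0.23), did not pass. In the DROSHA-independent list only miR-484 was lower, also adjusted over the list alone, and miR-320a (−0.19 ± 0.12) and miR-320b (0.00 ± 0.19) did not pass; the list median of −0.08 was 0.09 with library totals and 0.05 with upper-quartile factors. The camera test with its preset correlation had adjusted p values of 0.0039 for the mirtrons and 0.0013 for the DROSHA-independent list, which became 0.768 for both with an estimated correlation and 0.099 and 0.272 without WT replicate 1. By fry, which tests for a shift in 1 direction against no change, they were 0.190 and 0.112. By fry's mixed test, for changes in either direction, they were 0.034 and 0.0018.

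In HEK293T, AA lowered miR-484 by 73.1-fold, from 2198 ± 518 to 29.4 ± 6.1 CPM (n = 2 each). MiR-99b-5p fell 19.5-fold, from 671 ± 181 to 35.1 ± 8.19 CPM, its neighbour let-7e-5p (MIRLET7E, chromosome 19, 51692786 to 51692864, intron of SPACA6) 11.7-fold, from 305 ± 81.7 to 25.1 ± 9.09 CPM, and miR-331-3p 11.8-fold, from 394 ± 82.4 to 33.0 ± 3.1 CPM. The next largest falls among called miRNAs of at least 100 CPM were miR-151a-5p (−2.47 ± 0.18), miR-615-3p (−2.31 ± 0.22) and miR-324-3p (−2.08 ± 0.21). The largest rises with this limit were miR-30a-3p (1.51 ± 0.21), miR-30e-3p (1.39 ± 0.21), miR-625-3p (1.36 ± 0.20), miR-182-5p (1.28 ± 0.18), miR-181a-2-3p (1.23 ± 0.20), miR-10b-5p (1.15 ± 0.18) and miR-31-3p (1.15 ± 0.17), of which the first 5 were also called higher on the spike-in scale (0.73 to 1.02). With the spike-in total miR-30a-3p kept its call (0.79), and miR-30e-3p (0.68), miR-625-3p (0.64), miR-182-5p (0.57) and miR-181a-2-3p (0.50) did not. None of the 6 most abundant miRNAs passed: miR-19b-3p stood at 0.30 ± 0.16, miR-92a-3p at 0.34 ± 0.15, miR-10a-5p at 0.44 ± 0.16, miR-16-5p at −0.18 ± 0.15, miR-20a-5p at −0.16 ± 0.17 and miR-4521 at 0.17 ± 0.26. MiR-324-5p (−0.05 ± 0.19) and miR-451a (−0.13 ± 0.25) did not pass either. The edgeR adjusted p values were 1.1e-07 for miR-484, 3.7e-06 for miR-99b-5p, 3.2e-05 for let-7e-5p, 3.2e-05 for miR-331-3p, 9.1e-05 for miR-324-3p and 7.6e-04 for miR-30a-3p.

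By edgeR with Benjamini-Hochberg adjustment 39 of 626 miRNAs were higher and 95 lower with AA in HEK293T. Fewer were called without AA replicate 2 or without WT replicate 1. Such fits leave 1 library in a group and have less power, so this need not mean that effects moved. The split depended on the scaling: 57 higher and 82 lower with DESeq2 size factors (median −0.03), 129 and 41 with upper-quartile factors (median 0.34), 8 and 190 with the spike-ins (median −0.58) and 2 and 290 with the spike-in total (median −0.83), against a median of −0.11 with TMM. No spike-in was called in this comparison by edgeR, 7 of the 30 had an unadjusted p under 0.05, and the largest spike-in change was 1.32. Tested by glmTreat against that change 11 miRNAs were lower, among them miR-484, miR-99b-5p, let-7e-5p, miR-331-3p and miR-324-3p, and none higher.

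With AA in HEK293T, 9 of 14 members of the let-7 family were lower (10 adjusted over the list alone), with a median of −0.99; let-7a-5p was at −1.25 ± 0.24 and let-7f-5p at −0.96 ± 0.27, and let-7c-5p (−0.68 ± 0.24) did not pass. All 5 of the DROSHA-independent list fell (5 adjusted over the list alone), with miR-320a at −0.98 ± 0.21 and miR-320b at −0.97 ± 0.20. The median of each of these lists was below 0 under each of the 6 scalings. Of the miR-30 family 4 of 11 were higher (4 adjusted over the list alone), with miR-30a-5p at 0.80 ± 0.18 and miR-30e-5p, not called, at 0.38 ± 0.16. Of the p53-responsive list 5 of 14 were higher (6 adjusted over the list alone), with miR-194-5p at 0.75 ± 0.17 and miR-34a-5p, not called, at 0.11 ± 0.16. The medians of the miR-30 family (0.38) and the p53-responsive list (0.44) became −0.09 and −0.02 with spike-in scaling and −0.33 and −0.26 with the spike-in total. The calls of miR-320a (−0.89), miR-320b (−0.99), let-7a-5p (−1.02), let-7f-5p (−0.66) and miR-194-5p (0.79) were lost without AA replicate 2, that of let-7f-5p (−0.59) without WT replicate 2, and those of miR-30a-5p (0.60) and miR-194-5p (0.60) without WT replicate 1. The camera test with its preset correlation had adjusted p values of 6.7e-04 for the let-7 family, 1.0e-06 for the DROSHA-independent list, 0.0033 for the miR-30 family and 0.0023 for the p53-responsive list, which with an estimated correlation became 0.779, 0.400, 0.779 and 0.779. By fry, for a shift in 1 direction against no change, they were 0.055, 0.027, 0.067 and 0.077. By fry's mixed test, for changes in either direction, they were 0.0091, 2.1e-04, 0.0089 and 0.017.

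The share of reads that came from the 5p arm of a hairpin changed with both altered forms. This ratio within each library compares the 2 arms and does not say whether the favoured arm gained or the other was lost. With WT in HCT116, 9.39 ± 1.55% of miR-331 reads came from the 5p arm (mean ± SD, n = 2), against 95.7 ± 0.612% with dsRBD deletion and 38.1 ± 3.57% with AA. In HEK293T the miR-331 shares were 16.8 ± 3.47%, 80.8 ± 15.3% and 70.6 ± 1.06%. The deletion libraries there held 1 and 9 reads of miR-331-3p, so the 80.8% rests on few reads. The 5p arm of miR-331 also fell there (log2 fold change −2.57). The 5p share of miR-25 rose from 0.925 ± 0.156% to 62.6 ± 4.44% with dsRBD deletion in HCT116 and from 1.21 ± 0.121% to 36.8 ± 0.239% in HEK293T. That of miR-324 rose from 63.3 ± 1.96% to 80.8 ± 2.9% with the deletion and 75.8 ± 0.291% with AA in HCT116, and from 49.9 ± 1.06% to 79.5 ± 0.342% and 79.9 ± 3.34% in HEK293T. MiR-99b moved the other way with AA, from 91.8 ± 0.323% to 77.5 ± 1.31% in HCT116 and from 91.3 ± 2.15% to 73.9 ± 2.96% in HEK293T. The adjusted p values of the edgeR arm interaction for miR-331 were 2.2e-16 (deletion) and 1.1e-08 (AA) in HCT116 and 2.5e-06 and 6.0e-08 in HEK293T.

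**Figure D4:**
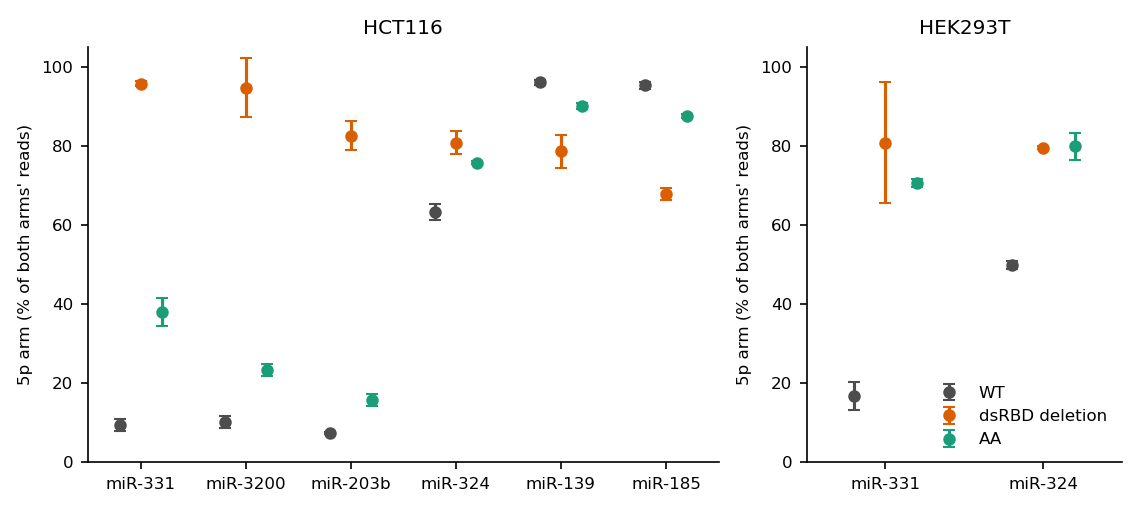
Share of reads from the 5p arm (y axis, percent of the reads of both arms) for named hairpins with WT, dsRBD deletion and AA in HCT116 and HEK293T, as means and SD of 2 libraries. The 5p share of miR-331 rose from 9.39% with WT to 95.7% with dsRBD deletion in HCT116 and from 16.8% to 80.8% in HEK293T, and that of miR-185 fell from 95.4% to 67.8% in HCT116. The HEK293T deletion libraries held 1 and 9 reads of miR-331-3p.

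With dsRBD deletion in HCT116 the 5p shares of miR-3200 (from 10.2% to 94.7%), miR-203b (from 7.41% to 82.6%) and miR-1277 (from 81.2% to 99.7%) also rose, and those of miR-185 (from 95.4% to 67.8%) and miR-139 (from 96.1% to 78.6%) fell. The deletion libraries of HCT116 held 0 and 4 reads of miR-3200-3p. In HEK293T the deletion moved miR-454 (from 5.18% to 44.9%) and miR-101 (from 0.537% to 10.2%) toward the 5p arm and miR-425 (from 95.9% to 61.5%), miR-629 (from 86.5% to 42.6%) and miR-93 (from 97.5% to 81.2%) toward the 3p arm. By TMM log2 fold change the arm that gained share was itself lower for miR-454 (−0.47), miR-425 (−0.80) and miR-93 (−3.23). It was higher for miR-101 (1.07) and miR-629 (0.46). On the spike-in scale the log2 fold change of the gaining arm was negative for both, at −0.38 for miR-101 and lower still for miR-629. AA moved miR-584 (from 93.3% to 98.4%) and miR-361 (from 78.0% to 89.4%) toward the 5p arm in HCT116, and miR-625 (from 28.8% to 14.2%) toward the 3p arm in HEK293T. Of 229 hairpins tested in HCT116, the edgeR arm interaction with Benjamini-Hochberg adjustment called 107 toward the 5p and 36 toward the 3p arm with dsRBD deletion, and 20 and 11 with AA. Of 180 in HEK293T it called 54 and 50 with dsRBD deletion and 9 and 10 with AA. Among 154 hairpins tested in both lines, the deletion called 59 in both, 49 of them in the same direction and 10 in opposite directions; 36 moved toward the 5p arm in both, where independent calls would give 23.7, and 13 toward the 3p arm, against 7.17. The AA counts depended on the method: limma on log2 ratios called 2 in HCT116 and 3 in HEK293T, and a replicate block left 9 in HCT116. The AA count in HCT116 was 14 to 18 without any 1 of its 4 libraries, against 31 with all of them, and that in HEK293T was 10 without WT replicate 1, against 19 with all. The miR-324 shift with AA in HCT116 lost its call without WT replicate 1 (0.77) or AA replicate 2 (0.84), from a log2 ratio change of 0.86 ± 0.19.

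The arms of a hairpin differ in sequence, and spike-ins of different sequence also moved apart. With dsRBD deletion in HEK293T, where 17 of the 30 spike-ins were called, they ranged from −1.21 to 1.63. Compared after the data were seen, 21 of the 104 arm changes called there exceeded this range of 2.83, among them miR-25 (5.58 ± 0.19), miR-331 (4.02 ± 0.55) and miR-425 (−3.85 ± 0.32) but not miR-324 (1.96 ± 0.26). With dsRBD deletion in HCT116, 83 of 143 exceeded a range of 1.63, among them miR-331 (7.72 ± 0.29) and miR-25 (7.49 ± 0.21) but not miR-324 (1.29). With AA in HCT116, where the spike-ins ranged from −0.91 to 2.09, 1 of 31 exceeded this range, miR-561, picked out after its value was seen. In HEK293T 3 of 19 exceeded a range of 2.06: miR-331 (3.58 ± 0.31), miR-561 (2.10, and 1.50 and not called without AA replicate 1) and miR-146b (−2.16, and −1.89 and not called without WT replicate 1).

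Whether the forms acted differently in the lines was tested as a difference of log2 fold changes, HEK293T minus HCT116, over 844 miRNAs. For dsRBD deletion miR-27a-3p differed by 3.82 ± 0.23 (n = 2 per group), having fallen in HCT116, and miR-93-5p by −4.58 ± 0.28, having fallen far more in HEK293T. Among called miRNAs of at least 100 CPM, miR-125b-5p (3.69 ± 0.36), miR-33b-5p (3.51 ± 0.34) and miR-193a-3p (3.26 ± 0.28) were more positive in HEK293T, and miR-340-5p (−5.09 ± 0.73), miR-224-5p (−4.24 ± 0.49) and miR-21-3p (−4.18 ± 0.34) more negative. For AA, with the same limit, the most negative differences were let-7e-5p (−2.58 ± 0.35), miR-99b-5p (−2.11 ± 0.29), miR-484 (−1.99 ± 0.29) and miR-151b (−1.81 ± 0.35), and the most positive were miR-145-5p (1.48 ± 0.34), miR-625-3p (1.45 ± 0.29), miR-182-5p (1.43 ± 0.27) and miR-30a-3p (1.40 ± 0.30). The limit is a mean over both lines, and in HEK293T miR-145-5p had only 27 and 38 reads with WT and 75 and 25 with AA. By edgeR with Benjamini-Hochberg adjustment 294 deletion effects differed (189 more positive in HEK293T, 105 more negative) and 33 AA effects (8 and 25); the adjusted p was 3.1e-11 for miR-27a-3p and for miR-93-5p and 9.7e-05 for let-7e-5p. The call of miR-145-5p was lost without WT replicate 1 (1.37) or AA replicate 1 (1.08) of HEK293T.

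The deletion split between the lines depended on scaling, from a median difference of 0.34 with TMM. It was 152 more positive and 136 more negative in HEK293T with DESeq2 size factors (median 0.03), 148 and 141 with upper-quartile factors (0.02) and 93 and 197 with library totals (−0.40). For AA the split was 19 and 25 with DESeq2 size factors (median 0.05), 7 and 71 with library totals (−0.40), 8 and 14 with spike-ins (−0.03) and 1 and 49 with the spike-in total (−0.43), against a median of −0.05 with TMM. The same test called 12 of the 30 spike-ins for the deletion, with differences of up to 2.01 in size, and 0 for AA by edgeR, where 2 had an unadjusted p under 0.05. The 8 miRNAs named for the deletion lay beyond the largest of the deletion's spike-in differences. Tested by glmTreat against that difference, 28 deletion effects were called. For AA the largest spike-in difference was 2.21, and of the 8 miRNAs named only let-7e-5p (−2.58) lay beyond it; none of the 8 was called by glmTreat against it.

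AA was also set directly against dsRBD deletion. In HCT116 miR-301a-3p stood at 1569 ± 33.7 CPM with AA and 38.6 ± 9.35 with the deletion (n = 2 each), a log2 fold change of 5.30 ± 0.20, and in HEK293T miR-93-5p stood at 17770 ± 623 and 233 ± 18.8 CPM (6.25 ± 0.21). Among called miRNAs of at least 100 CPM the largest rises also included miR-615-3p (6.72 ± 0.40), miR-3200-3p (5.90 ± 0.41) and miR-331-3p (5.05 ± 0.27) in HCT116, and miR-1269b (6.97 ± 0.36), miR-375 (6.23 ± 0.31) and miR-1180-3p (5.79 ± 0.36) in HEK293T. With this limit the largest falls were miR-25-5p (−2.78 ± 0.17), miR-30d-3p (−1.51 ± 0.14), miR-6087 (−1.43 ± 0.17) and miR-7641 (−1.40 ± 0.27) in HCT116, and miR-19a-5p (−3.69 ± 0.21), miR-1268a (−3.58 ± 0.46), miR-1268b (−3.47 ± 0.41) and miR-193a-3p (−3.10 ± 0.21) in HEK293T. By edgeR with Benjamini-Hochberg adjustment 235 were higher and 214 lower with AA in HCT116 (adjusted p 6.4e-09 for miR-301a-3p), and 226 and 231 in HEK293T (9.9e-09 for miR-93-5p). In HCT116 the split was 181 and 276 with library totals, 476 and 14 with spike-ins and 530 and 10 with the spike-in total; in HEK293T it was 322 and 99 with spike-ins and 289 and 131 with the spike-in total. The spike-ins called were 20 of 30 in HEK293T and 0 of 30 in HCT116, where 1 had an unadjusted p under 0.05. On the spike-in scale the falls of miR-30d-3p (−0.32), miR-6087 (−0.24) and miR-7641 (−0.22) in HCT116 were not called.

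Across miRNAs, which are not independent replicates, dsRBD deletion had similar effects in both lines. Of 539 miRNAs tested in both, 156 were lower in both where independent calls would give 82.8, 125 were higher in both against 66.2, and 35 were called in opposite directions; Pearson's r was 0.719 (bootstrap 95% interval 0.679 to 0.760) and Spearman's rho 0.701. For AA 30 were lower in both against 6.56, 1 higher in both against 0.445, and r was 0.552 (0.429 to 0.662) with a rho of 0.434. Within HCT116, 45 miRNAs were lower with both altered forms against 16.7 by independent calls and 5 higher against 2.81; within HEK293T, 82 were lower against 37.6, 14 higher against 14.0, and 20 were called in opposite directions. The correlation of the deletion and AA effects was 0.517 in HCT116 and 0.425 in HEK293T, where shared WT libraries alone gave 0.405 and 0.420 in simulated data with no effect. Their covariance was 0.464 against a simulated 0.0448 in HCT116 and 0.685 against 0.0451 in HEK293T. Each line has only 2 WT libraries, which could not be split between the comparisons, so part of these overlaps comes from shared controls. These are 4 correlations computed in 1 family.

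With WT DICER the lines themselves differed in which miRNAs they made. MiR-100-5p was at 7695 ± 291 CPM in HCT116 and 0.303 ± 0.429 in HEK293T (n = 2 each), miR-130a-3p at 3031 ± 131 and 0.460 ± 0.207, and miR-335-5p at 919 ± 151 and 0.768 ± 0.2. MiR-708-5p was at 763 ± 78.8 CPM in HEK293T and 0.275 ± 0.0336 in HCT116, miR-125b-2-3p at 458 ± 53.2 and 0.676 ± 0.111, and miR-3144-3p at 282 ± 60.3 and 1.82 ± 0.803. MiR-99a-3p had no reads with WT in HCT116 and was at least 243-fold higher in HEK293T, and miR-203a-5p had none in HEK293T and was at least 132-fold lower there, each against 3 reads per library (means of 0.826 and 0.925 CPM, scaled over all 12 libraries). By edgeR with Benjamini-Hochberg adjustment 270 of 844 miRNAs were higher in HEK293T and 348 lower (adjusted p 7.2e-19 for miR-100-5p and 9.9e-16 for miR-708-5p), and 85 and 577 with spike-in scaling or 85 and 584 with the spike-in total, whose medians were −2.02 and −2.05 against −0.39 with TMM. The test called 18 of the 30 spike-ins, with differences of up to 1.38 in size, all smaller than those of the miRNAs named here.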

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

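The comparison of rises with spike-in scaling, the shift given by single spike-ins, both counts against the largest spike-in difference and the exact chance were tests chosen after the results were seen, and the GC and minor-arm tests were chosen before.

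Effects of dsRBD deletion differed between HEK293T and HCT116 for 294 miRNAs by the edgeR test of the difference, among them miR-27a-3p (3.82), miR-125b-5p (3.69), miR-33b-5p (3.51), miR-193a-3p (3.26), miR-340-5p (−5.09), miR-93-5p (−4.58), miR-224-5p (−4.24) and miR-21-3p (−4.18). Of these, 127 (57 more positive in HEK293T and 70 more negative) lay beyond the largest difference of any spike-in, 2.01, where a preparation difference that moved miRNAs as it moved the spike-ins would put about 27.2 of the tested names. The 127 are counted by their estimates. Tested by glmTreat against that largest difference, also chosen after the results were seen, 28 were called. The limit set for the count of 127 was 3 times 27.2, 81.7, and if miRNAs and spike-ins were exchangeable the exact chance of 127 or more would be 0.0083. MiRNAs are not independent of each other and need not vary as spike-ins do. The count therefore does not decide whether a preparation difference moved these miRNAs. The other 167 cannot be told apart from a library preparation difference either, because the same test called 12 of the 30 spike-ins. Removing the GC trend lowered the SD of all differences by 0.467%, from 2.06 to 2.05, which argues against GC content. A biological difference between the cell lines, such as in their precursor levels, was not tested and stays open.

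Effects of AA differed between the lines for 33 miRNAs by the same edgeR test, among them miR-145-5p (1.48), miR-625-3p (1.45), miR-182-5p (1.43), miR-30a-3p (1.40), let-7e-5p (−2.58), miR-99b-5p (−2.11), miR-484 (−1.99) and miR-151b (−1.81), of which only let-7e-5p lies beyond the largest spike-in difference, 2.21. The spike-ins, which are no part of the miRNA comparisons, also moved against each other: 17 of the 30 were called with dsRBD deletion against WT in HEK293T, 20 with AA against dsRBD deletion in HEK293T, 12 in the difference of deletion effects between lines and 18 between the lines with WT.

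Of the 223 miRNAs that rose with dsRBD deletion in HCT116 by TMM, 7 were also called higher on the spike-in scale and 105 were called lower on it. Spike-in scaling moves every miRNA by about the same −1.76, so these counts do not decide whether a global fall of miRNA reads lifted miRNAs that were unchanged, and that stays open. Unequal recovery of some spike-ins was argued against as the source of that fall, since each of the 30 taken alone gave a log2 shift from −2.27 to −0.783. In HEK293T the same range reached −0.249, past the limit of −0.5 set for this test, so unequal recovery is not excluded there. A different amount of spike-in RNA added to these libraries would move all 30 alike and stays open, because the amount is not given in the sources used here.

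In both lines most arm shifts with dsRBD deletion went toward the arm that was minor with WT, for 72.7% of 143 called hairpins in HCT116 and 76.0% of 104 in HEK293T. The same WT libraries served the test and the choice of the minor arm, so that arm was also taken from the other line. The shares were 80.6% (exact 95% interval 72.7 to 87.0, 104 of 129) in HCT116 and 66.7% (56.5 to 75.8, 66 of 99) in HEK293T. The deletion libraries were shallower than the WT libraries in both lines, so a fall of a scarce arm is harder to call than a rise. The share that this alone would give was not computed, and the intervals treat hairpins as independent. These shares therefore do not decide whether noise in the WT libraries gave the pattern. A change in strand choice, a change in where DICER cuts and a preparation difference between sequences, as seen in the spike-ins, were not tested for this pattern and stay open.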

How the results depend on the processing

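The spike-in scalings, the test against the largest spike-in change and the crossed replicate numbers were tests chosen after the results were seen. Of 3838 values of 262 named results under alternatives, 3469 kept direction and side of the threshold, 93 newly passed, 236 no longer passed and 40 reversed; of the counts, correlations and ratios 202 were within their limits and 47 moved. Causes were not tested except where fewer names were tested or the scaling itself sets the direction.

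With a mean of at least 100 CPM, which leaves fewer names, the calls were 226 for dsRBD deletion in HCT116, 27 for AA in HCT116, 217 for AA against deletion in HCT116, 224 for dsRBD deletion in HEK293T, 211 for AA against deletion in HEK293T, 174 for the difference of deletion effects and 229 between the lines with WT. There were 5 list calls, the correlations were 0.598 (deletion and AA in HCT116), 0.778 (deletion in both lines) and 0.743 (AA in both lines), and miR-10a-5p with dsRBD deletion in HEK293T was 0.39. By glmTreat against the largest spike-in change, in the same order, the calls were 193, 1, 85, 212, 93, 28 and 336, with 11 for AA in HEK293T and 0 for the AA difference. AA in HCT116 had 34 calls with upper-quartile factors, 38 with the spread shared by all 12 libraries, 272 with spike-ins and 186 with the spike-in total. AA in HEK293T had 292 with the spike-in total, and the AA difference 78 with library totals and 50 with the spike-in total. The ratio of AA to WT in HEK293T by the median of spike-in ratios was −0.44 on the log2 scale.

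For arms, at least 50 reads in every library left 63 calls for dsRBD deletion in HCT116, 12 for AA in HCT116 and 50 for dsRBD deletion in HEK293T, of fewer hairpins, and limma gave 2 for AA in HCT116 and 3 for AA in HEK293T. Camera with an estimated correlation called 0 of the 9 lists called with the preset one, and fry called 27 lists, of which 3 were among those 9; the other 6 of the 9 did not pass by fry, which tests a list against no change rather than against the other miRNAs.

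With library totals, values for dsRBD deletion vs WT in HCT116 reversed for miR-21-5p (0.48), let-7a-5p (0.42), miR-92a-3p (0.0046) and miR-30e-5p (0.13). Scaled to the spike-ins (median of ratios), and scaled to the spike-in total, they reversed for miR-7974 (−0.0600, −0.0419), miR-1268a (−0.0609, −0.0584), miR-1268b (−0.0652, −0.0624), miR-451a (−0.59, −0.58), let-7g-5p (−1.32, −1.31), miR-10a-5p (−0.86, −0.85), miR-100-5p (−1.13, −1.12), miR-19b-3p (−1.35, −1.34), miR-181a-5p (−1.57, −1.57), miR-181b-5p (−1.76, −1.75), miR-30d-5p (−1.09, −1.08), miR-877-5p (−1.61, −1.61) and miR-877-3p (−1.30, −1.31). They reversed for dsRBD deletion vs WT in HEK293T for miR-4521 (−0.16, −0.13), miR-324-5p (−0.82, −0.80), let-7c-5p (−0.89, −0.85) and miR-877-5p (−1.45, −1.42), and for AA vs WT in HEK293T for miR-181a-5p (−0.0513, spike-in total only).

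Leaving out each library in turn, where a lone library is assumed to vary like the other groups, gave 417 to 466 calls for dsRBD deletion in HCT116, 10 to 73 for AA in HCT116 (10 and 23 without AA replicate 1 and 2), 312 to 393 for AA against deletion in HCT116, 425 to 448 for dsRBD deletion in HEK293T, 54 to 136 for AA in HEK293T (54 without AA replicate 2, 88 without WT replicate 1), 394 to 414 for AA against deletion in HEK293T, 245 to 289 for the difference of deletion effects, 26 to 42 for that of AA effects and 573 to 602 between the lines with WT. Arm calls were 121 to 132, 14 to 18 (14 and 18 without WT replicate 1 and 2, 17 and 16 without AA replicate 1 and 2), 86 to 97 and 10 to 21 (10 without WT replicate 1) for dsRBD deletion and AA in HCT116 and then HEK293T, and list calls 7 to 11. Correlations were 0.449 to 0.520 for deletion and AA in HCT116 (0.454 and 0.449 without AA replicate 1 and 2), 0.363 to 0.473 in HEK293T, 0.684 to 0.740 for deletion in both lines and 0.488 to 0.539 for AA in both. The log2 ratio to WT of miRNA reads per spike-in read was −2.52 to −2.09 for deletion and −0.82 to −0.40 for AA in HCT116, and −1.59 to −1.49 and −0.88 to −0.47 in HEK293T. Fits with 1 library in a group have less power, so fewer calls there need not mean smaller effects.

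With a replicate block, calls were 478 for dsRBD deletion vs WT in HCT116, 46 for AA vs WT in HCT116 and 421 for AA vs dsRBD deletion in HCT116, with 480, 155 and 461 in HEK293T, 281 and 29 for the differences of deletion and AA effects, and 547 between the lines with WT. Arm calls were 130, 9, 103 and 23, and list calls 10. With the AA numbers crossed, AA in HCT116 had 78 calls, 15 higher and 63 lower. The shallowest library held 824987 miRNA reads, so that 3 reads were 3.10 CPM there.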

Other observations

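The tests of names without an arm suffix were chosen after the results were seen, and those of the hairpin motif before.

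Other families split or fell with dsRBD deletion in HCT116. MiR-145-5p (−1.76 ± 0.14) and miR-34a-5p (−1.24 ± 0.11) fell, and with them 4 of 14 p53-responsive miRNAs were lower and none higher. MiR-200a-3p fell by 2.88 and miR-200b-3p by 1.04, with 3 of 8 in the miR-200 family higher and 4 lower. MiR-10a-5p (0.95 ± 0.12) and miR-100-5p (0.66 ± 0.11) rose, with 6 of 13 in their family higher and 4 lower, and miR-30d-5p rose by 0.71, with 6 of 11 in the miR-30 family higher and 4 lower. The higher and lower members were 3 and 3 of 9 in the miR-181 family, 2 and 4 of 14 in the miR-15 and miR-16 family, 1 and 3 of 5 in the miR-148 and miR-152 list, 0 and 4 of 6 in the miR-183 cluster, 1 and 3 of 4 in miR-221 and miR-222, 2 and 2 of 5 in miR-26 and 4 and 3 of 7 in miR-29. They were 0 and 5 of 8 in C19MC, 2 and 9 of 24 in the chromosome 14q32 cluster, 2 and 6 of 15 mirtrons, and 4 and 1 of 10 markers of other tissues. Adjusted over the list alone, these counts changed to 1 and 4 for miR-148 and miR-152 and to 1 and 9 for chromosome 14q32, and the others had the same counts. Median and mean differed in sign for the miR-10 list (0.63 and −0.35), miR-29 (0.75 and −0.65), miR-15 and miR-16 (0.13 and −0.13), miR-181 (0.19 and −0.13) and the p53-responsive list (0.11 and −0.08). With spike-in scaling each of these 5 medians was below 0, from −1.67 to −1.04, as were those of miR-30 (0.41 to −1.39) and the markers of other tissues (0.81 to −0.98), and with library totals those of miR-200 (−0.43 to 0.10), miR-183 (−0.51 to 0.01) and miR-26 (−0.31 to 0.22) rose above it. By camera none of these lists was called, with an adjusted p of 0.805 for miR-148 and miR-152 and 0.939 for the others, except miR-221 and miR-222, whose 4 names were too few to test.

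In HEK293T, dsRBD deletion lowered miR-34a-5p by 3.07 and miR-141-3p by 4.19, and raised miR-877-3p by 1.52 (0.07 by spike-ins). Higher and lower members were 7 and 3 of 14 p53-responsive miRNAs, 5 and 3 of 12 in the miR-10 list, 9 and 9 of 21 in the miR-17-92 list, 2 and 6 of 14 in let-7, 4 and 7 of 15 in miR-15 and miR-16, 0 and 3 of 4 in miR-200, 1 and 3 of 6 in miR-183, 0 and 3 of 4 in miR-221 and miR-222, 1 and 3 of 5 in miR-26, 2 and 5 of 7 in miR-29, 1 and 0 of 4 mirtrons and 4 and 3 of 9 markers of other tissues. They were 77 and 113 of 252 3p names and 88 and 105 of 256 5p names (88 and 104 adjusted over the list alone); the other lists here had the same counts adjusted over the list alone. Median and mean differed in sign for the miR-10 list (0.26 and −0.10) and the mirtrons (−0.21 and 0.13). With spike-ins the medians of the p53-responsive list (0.76), the miR-10 list and the markers of other tissues (0.34) became −0.70, −1.20 and −1.11, and with upper-quartile factors those of let-7 (−0.31), miR-17-92 (−0.12) miR-15 and miR-16 (−0.09) and the mirtrons became 0.12, 0.31, 0.34 and 0.22. No list was tested for chromosome 14q32 or C19MC, which had 0 names tested in HEK293T.

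With AA the camera test with its preset correlation called no other list in either line, while single members of several lists were called. In HCT116 the lower members were 3 of 19 in let-7 (4 adjusted over the list alone), 2 of 13 in the miR-10 list, 2 of 11 in miR-23, miR-27 and miR-24, and 1 each in the miR-17-92, miR-181 and miR-221 and miR-222 lists (2 of the last adjusted over the list alone), and 1 of 11 in miR-30 was higher. The 3p names had 6 higher and 24 lower (8 and 33 adjusted over the list alone) and the 5p names 0 and 19 (0 and 18). By edgeR no member was called in miR-15 and miR-16, miR-26, miR-29, miR-148 and miR-152, miR-183, miR-200, p53-responsive, C19MC, chromosome 14q32 or other-tissue lists, also adjusted over the list alone. In HEK293T miR-27b-3p fell by 1.92 and miR-23b-3p by 0.87, the last not called without WT replicate 1 (−0.63) or AA replicate 2 (−0.58). Higher and lower were 0 and 3 of 11 in their family, 2 and 5 of 21 in the miR-17-92 list, 2 and 2 of 12 in the miR-10 list (3 and 2 adjusted over the list alone), 2 and 2 of 9 in miR-181 (2 and 3), 1 and 1 of 6 in miR-183, 0 and 2 of 4 in miR-221 and miR-222, 0 and 1 of 7 in miR-29 (0 and 2), 0 and 1 of 15 in miR-15 and miR-16, 0 and 1 of 4 mirtrons and 1 and 0 of 9 markers of other tissues (0 and 0). They were 17 and 40 of 252 3p names (17 and 41) and 16 and 41 of 256 5p names, and none in miR-26, miR-148 and miR-152 or miR-200. Median and camera direction differed from the mean for the miR-10 list (0.16 and −0.30), miR-181 (0.02 and −0.06) and miR-26 (0.07 and −0.01), and for miR-183 the median (−0.15) from the camera direction, which was up. In HCT116 the median was above 0 and the mean below for let-7 (0.02 and −0.12) and miR-23, miR-27 and miR-24 (0.03 and −0.06), and for the miR-15 and miR-16, miR-17-92 and 5p lists the median was below 0 and the camera direction up. Library totals turned the medians of the miR-10 (−0.05), miR-15 and miR-16 (−0.03) and miR-183 (−0.17) lists in HCT116 to 0.13, 0.14 and 0.01, and spike-ins turned the positive medians there to −0.42 or lower. In HEK293T upper-quartile factors turned the medians of miR-17-92 (−0.25), miR-15 and miR-16 (−0.13), miR-183 (−0.15), miR-29 (−0.37) and miR-23, miR-27 and miR-24 (−0.31) to 0.20, 0.32, 0.30, 0.08 and 0.14, and spike-ins turned those of the miR-10, miR-181, miR-26 and other-tissue lists to −0.33, −0.43, −0.40 and −0.25.

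One hypothesis was that names without an arm suffix, which mostly lack a second annotated arm, fall less with dsRBD deletion because fewer of their reads are cut by DICER. Their median log2 fold change was 0.57 against −0.09 for names with a suffix in HCT116 (145 and 650 names), a difference of 0.66 (bootstrap 95% interval 0.15 to 1.14, permutation adjusted p 0.0032). In HEK293T it was 0.78 against −0.35 (118 and 508 names), a difference of 1.12 (0.56 to 1.63, permutation adjusted p 6.0e-04). On the spike-in scale both kinds of name fell, with medians of −1.17 and −1.86 in HCT116 and −0.67 and −1.79 in HEK293T. The association could have other sources, such as low abundance, which were not tested.

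A second hypothesis was that hairpins with a paired G, a paired pyrimidine and an unpaired C or A within 12 nt of the terminal loop respond differently. The mean log2 fold change of the major arm differed, hairpins with minus without the pattern, by 0.0568 (95% interval −0.37 to 0.47) with dsRBD deletion and 0.0207 (−0.09 to 0.13) with AA in HCT116 (104 hairpins with, 455 without), and by 0.21 (−0.34 to 0.75) and 0.12 (−0.05 to 0.29) in HEK293T (84 and 359). The permutation adjusted p was 0.793 in each. The pattern was placed on the predicted fold of the hairpin and not on the DICER site, so it tests a loose form of the idea only.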
